A study of Homo sapiens with 6 samples.

How the data were processed

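Gene expression was measured by RNA sequencing in 6 samples of HCT116, an established human colorectal carcinoma cell line. There were 3 control samples that received DMSO and 3 samples treated with irinotecan (CPT-11) at 10 µM for 48 hours. Groups and replicate numbers were taken from the sample labels; the series text speaks of duplicates, but the labels give 3 samples per group, and all were used. Total RNA was extracted with Trizol and its integrity inspected on a Bioanalyzer, per the labels' protocols; the method of mRNA selection, strandedness and read length are not given in the sources used here.

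The submitters' processing notes name fastp 0.19.3, HISAT2 2.1.0, featureCounts 1.6.2, StringTie 1.3.4d, DESeq2 1.22.1 and edgeR 3.24.3, and the human genome build GRCh38, without saying which tool made which value. One table of 30560 genes was analysed. Its gene starts and ends were equal to those of GENCODE release 29 on GRCh38 for 30560 of 30560 genes. Every listed gene had at least 2 reads over the 6 libraries. The per-sample values the authors deposited are a normalized signal per gene that is never negative, called the normalized count here. In each library 100% of these values were whole multiples, within 0.001 read, of what 1 read was worth, so they are read counts divided by 1 size factor per library, and the whole reads could be recovered. The authors also deposited a log2 fold change and a p-value with its adjusted value for each gene, per the file headers. The method behind those is not stated there, and they are quoted only as the authors' own. How reads on overlapping genes, or reads that align to several places, were counted is not given in the sources used here, so genes that share exons with a neighbour or sequence with a close relative are uncertain.

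The recovered totals ran from 15398464 to 18031195 reads on genes per library. A floor of 3 reads then equals 0.166 to 0.195 CPM (counts scaled by the library total); such limits cover counting error only, since no source used here mentions molecular identifiers.

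The test was chosen before the data were examined as edgeR on counts, or limma on log values if the table held none. As the table holds normalized counts, the main test was limma 3.58.1 with a mean-variance trend in R 4.3.3, on log2(normalized count + 1). Although whole reads could be recovered, the planned edgeR test was run on them only as an alternative. Genes with a mean of at least 10 normalized counts over the 6 samples entered, which left 16239, and a gene was called changed at a Benjamini-Hochberg adjusted p below 0.05. A gene averaging below 10 in 1 group entered only if the other group was higher, so the filter fixed its direction. The added 1 makes the fold change of genes with few reads smaller than the ratio of their counts. Fold changes are CPT-11 against control, each adjusted p of a gene comes from this limma fit, and a value after ± is an SD over 3 samples unless SE is written.

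Before the data were examined, 26 gene lists were fixed: 10 primary, 11 secondary, 2 on RNA quality and 3 of markers of other cell types. Of 861 list entries 788 had a row; the others are not analysed here. The 23 lists with at least 5 tested members were tested with camera, on the same log2 values, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. The test was repeated with a correlation estimated for each list, and fry was run beside it. Counts of members that rose or fell use the adjustment over all tested genes; counts adjusted over the list alone are given beside them.

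Genes were named by a rule set at the same time. It takes the 6 most raised and 6 most lowered protein-coding genes with a mean of at least 10 CPM and no overlap between groups. It adds the 2 most changed members of each primary list and the most changed member of each secondary list, at a mean of at least 1 CPM. Further genes were named whatever their result, among them TOP1, CDKN1A, CGAS, STING1, IFNB1, CD274, MICB, CXCL10 and CCL5. Some items that the rule takes are not reported here. Every other gene named in the text was chosen after its values were seen.

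The tests were run on simulated reads with the means and library sizes of these 6 samples. For CPT-11 against control, over 16131 simulated genes, limma recovered 66% of genes changed 1.5-fold, 86% of those changed 2-fold, 94% at 4-fold and 96% at 8-fold, with 50 genes at each size. Of its 175 calls 4 were unchanged genes. In that simulation no other gene was changed, whereas 49.4% of tested genes changed in the data, so these rates may not carry over. camera called 1 of 100 unchanged lists at p below 0.05. Simulated genes varied independently of each other, so this says nothing of false calls in lists of correlated genes.

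Alternatives covered the pseudocount, the filter, library scaling, the tool, the replicate number as a block, the correlation between genes, members shared between lists and leaving out each sample in turn. DESeq2 1.42.0, edgeR 4.0.16 and voom were run on the recovered reads. Genomic span was taken from the table's gene starts and ends, and transcript GC content and shared exonic bases from GENCODE release 29.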

Results

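The comparison sets irinotecan-treated HCT116 cells against DMSO controls, in a series whose title concerns anti-tumour immunity. Irinotecan (CPT-11) is a camptothecin prodrug, and its active metabolite traps topoisomerase I on DNA. Each group had 3 RNA sequencing libraries, with 16720393, 15673435 and 17110580 reads on genes in controls 1, 2 and 3, and 18031195, 16158933 and 15398464 in CPT-11 samples 1, 2 and 3. Protein-coding genes took 96.9% ± 0.13 (SD, n = 3) of these reads in controls and 95.9% ± 0.13 (SD, n = 3) after CPT-11. The mitochondrial chromosome took 7.24% ± 0.34 and 10.3% ± 0.62 (SD, n = 3). Libraries numbered 1 stood apart within both groups: the chi-square of read counts per degree of freedom was 11.5 and 11 against the other controls and 3.86 between those, and 8 and 10.8 against 3.19 in the CPT-11 group, so no library was a copy of another. The labels do not say whether the samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

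After 48 hours of CPT-11, 52 of 57 measured p53 target genes were higher and 46 of 48 genes of G1/S and DNA replication lower, in a change that took in 49.4% of the tested genes. CDKN1A, which encodes the cell cycle inhibitor p21, rose 6.92-fold, while all 40 measured G2/M and mitosis genes fell. Of the immune lists, 23 of 44 interferon-stimulated genes rose and 4 fell. On the list of T cell and NK cell ligands, which also holds receptors such as FAS, 17 of 32 rose and 7 fell. Of cytokines 10 of 19 rose and 2 fell. ISG15 rose 3.26-fold, FAS 3.77-fold and GDF15 4.69-fold. Both FAS and GDF15 are also on the p53 target list. Without members that other lists hold, the ligands and cytokines did not pass (adjusted p = 0.083 and 0.0779). Nucleic acid sensing (6 of 19 higher and 5 lower, adjusted p = 0.429), MHC class I (6 of 20 higher and 3 lower, 0.167) and NF-kB genes (9 of 22 higher and 2 lower, 0.0703) did not pass as lists. Of double-strand break repair genes 28 of 45 fell, and of cholesterol synthesis genes 17 of 24. The p53, cell cycle, interferon, ligand, cytokine, repair and cholesterol lists passed with a preset correlation between genes, and had adjusted p from 0.0619 to 0.139 with an estimated correlation. In all, 8022 of 16239 tested genes changed at an adjusted p below 0.05 (limma), 3939 higher and 4083 lower, and 2271 of them changed at least 2-fold (1065 higher and 1206 lower). The 2 groups did not overlap in 56.6% of tested genes, where chance gives 10%. The first principal component held 73.4% of the variance and parted the groups. The authors' deposited table lists 7481 genes at an adjusted p below 0.05, and 7171 of the 8022 calls are among them with the same direction and 0 with the opposite one.

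The 6 most raised genes with a mean of at least 10 CPM were KRTAP3-1, HRNR, CEACAM1, COL17A1, PTAFR and CPA4. KRTAP3-1, a hair keratin-associated protein gene (chromosome 17, 41008521 to 41019324 on GRCh38), went from 7 reads over the 3 controls to 8591 over the 3 CPT-11 libraries, or from 2.2 ± 3 to 2801 ± 94.8 normalized counts (n = 3). HRNR (chromosome 1, 152212082 to 152224193), which encodes hornerin of the cornified skin layer, had 5.0 ± 0.7 and 364 ± 20 (log2 fold change 5.94, SE 0.23). CEACAM1, an adhesion molecule that also inhibits T cells and NK cells (chromosome 19, 42507304 to 42561234), had 17.7 ± 8.4 and 818 ± 43.7 (log2 fold change 5.54, SE 0.23). COL17A1, a hemidesmosome collagen, rose by 4.87, PTAFR, the platelet-activating factor receptor, by 4.36, and the carboxypeptidase gene CPA4 by 4.24 on the log2 scale. KRTAP3-1, HRNR and CEACAM1 belong to families with closely related sequences, so reads shared with relatives are a source of uncertainty. Adjusted p lay between 7.06e-15 and 6.44e-12 for these 6 genes.

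The 6 most lowered genes were all long ones, spanning 426 to 1900.3 kb of the genome, against a median of 32.9 kb for tested protein-coding genes. LRP1B, a large lipoprotein receptor relative (chromosome 2, 140231423 to 142131701), fell from 581 ± 57.7 to 10.0 ± 2.7 normalized counts (n = 3), a log2 fold change of -5.75 (SE 0.22). SYT1, the synaptotagmin that senses calcium in vesicle release (chromosome 12, 78863993 to 79452008), fell from 2425 ± 277 to 152 ± 24.8 (log2 fold change -3.99, SE 0.13). PTPRG, a receptor tyrosine phosphatase, was 9.47-fold lower, EXOC4, an exocyst subunit, 8.08-fold, MAGI1, a junction scaffold, 7.73-fold, and PCDH7, a protocadherin, 7.63-fold. Adjusted p lay between 3.2e-13 and 4.41e-11.

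Fold changes differed with the genomic span of a gene. Of 452 tested protein-coding genes spanning at least 300 kb, 355 fell and 29 rose, with a median log2 fold change of -1.08. Of 2490 genes under 10 kb, 400 fell and 847 rose, with a median of 0.16. In genes of 300 kb or more the median against the controls was -1.15, -1.07 and -1.06 in CPT-11 samples 1, 2 and 3.

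**Figure D1:**
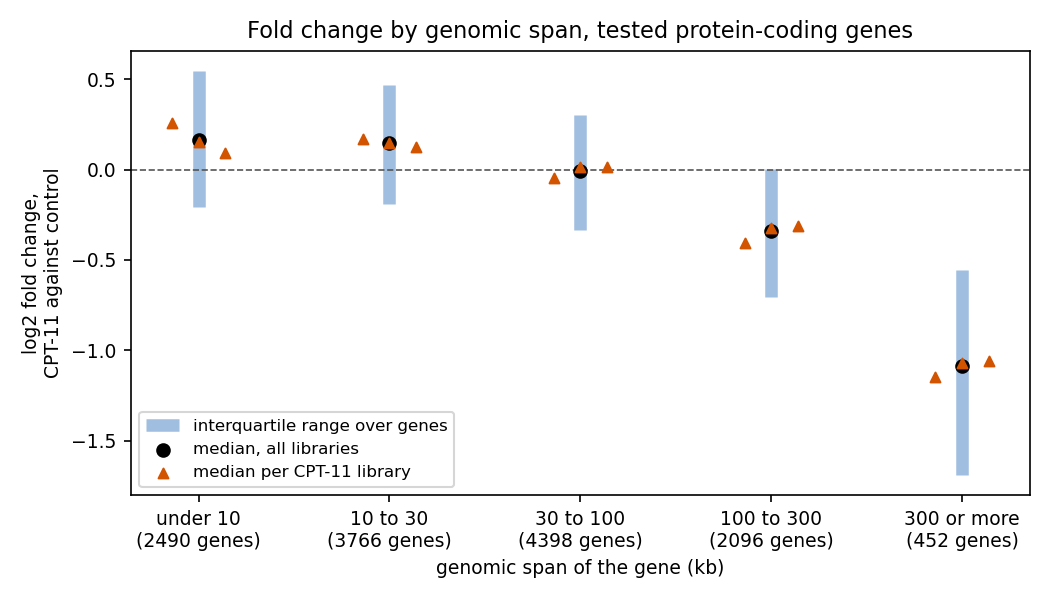
Log2 fold change of CPT-11 against control (vertical axis) by genomic span in kb (horizontal axis) for tested protein-coding genes. Dots are medians over genes, bars interquartile ranges over genes and triangles the median of each of the 3 CPT-11 libraries against the control mean; the median falls from 0.16 under 10 kb to -1.08 at 300 kb or more.

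Of 57 measured p53 target genes, 52 rose, 2 fell and 3 did not pass (52 and 2 adjusted over the list alone), with a mean log2 fold change of 1.33. The list stood apart from other genes with camera's preset correlation (adjusted p = 3.08e-26), and had adjusted p = 0.0619 with an estimated correlation. CDKN1A (ENSG00000124762, chromosome 6, 36676460 to 36687339) went from 4774 ± 355 to 33060.2 ± 3084 normalized counts (n = 3), a log2 fold change of 2.79 (SE 0.09, adjusted p = 4.95e-13). TP53I3, a quinone oxidoreductase, rose 13.8-fold and TRIM22, an antiviral ubiquitin ligase, 9.44-fold. The members that fell were KITLG, the KIT receptor ligand (-2.70), and POLK, a translesion polymerase (-0.35); POLK did not pass when libraries were scaled by size alone or without mitochondrial genes.

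All 40 measured G2/M and mitosis genes fell (40 adjusted over the list alone), with a median log2 fold change of -1.45. camera gave adjusted p = 4.75e-27, and adjusted p = 0.0726 with an estimated correlation. The spindle checkpoint kinase genes TTK (-1.94, SE 0.12) and BUB1B (-1.91, SE 0.11) were the named members. Of 48 G1/S and DNA replication genes, 46 fell and 2 rose (46 and 2 adjusted over the list alone), with a median of -1.16. The list had adjusted p = 3.21e-23, and adjusted p = 0.0726 with an estimated correlation. POLA1, the catalytic subunit of DNA polymerase alpha, had a log2 fold change of -2.33, and MCM5, part of the replicative helicase, fell from 2905 ± 272 to 684 ± 38.7 normalized counts (log2 fold change -2.08, SE 0.10). The members that rose were PCNA, the sliding clamp used in replication and repair (0.78), and CCNE1, cyclin E1 (0.36).

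**Figure D2:**
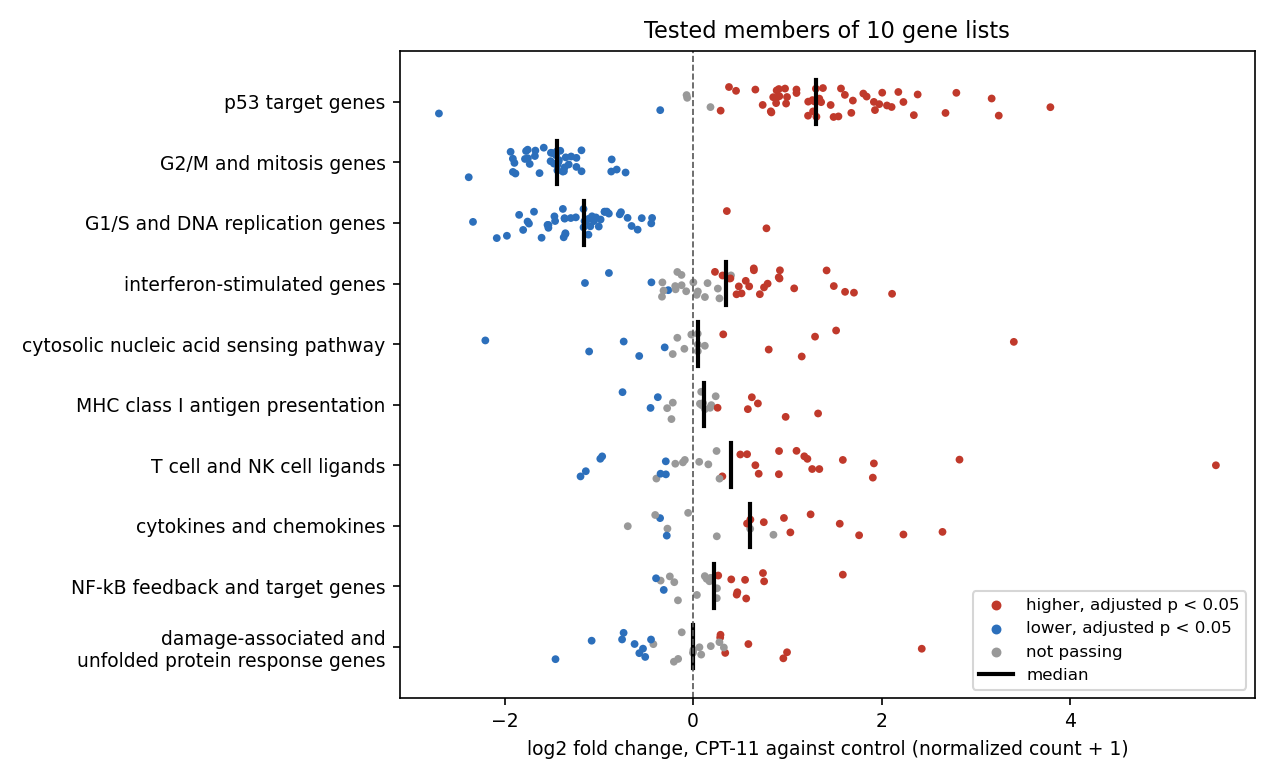
Log2 fold change of CPT-11 against control on log2(normalized count + 1) (horizontal axis) of each tested member of the 10 primary gene lists (rows), with black bars at the list medians; colour gives the direction of genes at an adjusted p below 0.05 and grey the rest. All 40 G2/M and mitosis genes lie between -2.38 and -0.72, while the lists on immune recognition lie on both sides of 0.

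Of 44 measured interferon-stimulated genes, 23 rose, 4 fell and 17 did not pass (24 and 4 adjusted over the list alone), with a median log2 fold change of 0.35. camera gave adjusted p = 0.000848, and adjusted p = 0.0979 with an estimated correlation; the median was 0.22 once the trend of fold change with genomic span was removed. LAMP3, a lysosomal membrane protein of mature dendritic cells, rose by 2.11 (SE 0.13) and ISG15, a ubiquitin-like modifier, by 1.70 (SE 0.10), from 1137 ± 96.8 to 3721 ± 478 normalized counts (n = 3).

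Of 19 measured genes of cytosolic nucleic acid sensing, 6 rose, 5 fell and 8 did not pass (6 and 5 adjusted over the list alone), and the list did not stand apart (median 0.05, 0.01 without the span trend and 0.13 with mitochondrial genes left out of the scaling; camera adjusted p = 0.429). TLR3, the endosomal receptor for double-stranded RNA, rose from 71.1 ± 7.8 to 762 ± 112 normalized counts (log2 fold change 3.40, SE 0.15). STING1, listed as TMEM173 (chromosome 5, 139475534 to 139482935), the adaptor that responds to cyclic GMP-AMP, rose from 323 ± 38.7 to 924 ± 101 (log2 fold change 1.52, SE 0.12, adjusted p = 1.63e-08). CGAS, the enzyme that makes cyclic GMP-AMP, had 5 reads over the controls and 17 over the CPT-11 libraries and was not tested. RNASEH2A, a subunit of ribonuclease H2, had a log2 fold change of -2.20 (SE 0.39), but shares 30.8% of its exonic bases with another gene, so its count is uncertain. IFNB1 and CXCL10 were not analysed here.

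Of 20 measured genes of MHC class I antigen presentation, 6 rose, 3 fell and 11 did not pass (6 and 3 adjusted over the list alone), and the list did not stand apart (median 0.12, 0.05 without the span trend and 0.20 with mitochondrial genes left out of the scaling; camera adjusted p = 0.167). TAP1, a subunit of the peptide transporter, rose from 786 ± 45.9 to 1977 ± 251 normalized counts (log2 fold change 1.32, SE 0.10), and the peptide-trimming enzyme ERAP2 by 0.98 (SE 0.17).

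Of 32 measured members of the list of T cell and NK cell ligands, 17 rose, 7 fell and 8 did not pass (18 and 7 adjusted over the list alone), with a median log2 fold change of 0.41. With mitochondrial genes left out of the scaling, 18 rose and 4 fell, with a median of 0.49. RAET1L, which rose from 3.61 ± 2.47 normalized counts in controls, entered the test through the CPT-11 group alone. camera gave adjusted p = 0.00565, adjusted p = 0.094 with an estimated correlation, and adjusted p = 0.083 without the 4 members that other lists hold. Besides CEACAM1, FAS, the death receptor engaged by cytotoxic lymphocytes, rose from 291 ± 23.7 to 1100 ± 84.6 normalized counts (log2 fold change 1.92, SE 0.11). CD274, which encodes PD-L1, the ligand of the inhibitory receptor PD-1 (chromosome 9, 5450503 to 5470566), rose from 58.8 ± 1.2 to 112 ± 13.3 (log2 fold change 0.91, SE 0.19, adjusted p = 0.000618). MICB, a ligand of the NK receptor NKG2D, had 591 ± 26.8 and 702 ± 37.4 (log2 fold change 0.25, SE 0.10, adjusted p = 0.0531), and passed in 6 of 20 alternative settings.

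Of 19 measured cytokines and chemokines, 10 rose, 2 fell and 7 did not pass (10 and 2 adjusted over the list alone), with a median log2 fold change of 0.61. camera gave adjusted p = 0.0115, adjusted p = 0.122 with an estimated correlation, and adjusted p = 0.0779 without the 3 members that other lists hold. GDF15, a stress-induced cytokine that is also a p53 target, rose from 3454 ± 748 to 16000.3 ± 1750 normalized counts (log2 fold change 2.23, SE 0.13), and IL32, a proinflammatory cytokine, by 1.76 (SE 0.34) from 39 reads over the controls. IL1A (4.55 ± 4.11 normalized counts in controls) and IL1RN (6.53 ± 4.15), which rose, entered the test through the CPT-11 group alone. CCL5, a T cell attractant, had 7 and 11 reads and was not tested. Of 22 NF-kB feedback and target genes, 9 rose, 2 fell and 11 did not pass (9 and 2 adjusted over the list alone); the list had a median of 0.22 and did not pass (camera adjusted p = 0.0703), except without CPT-11 replicate 3 (adjusted p = 0.0268), and the median was 0.07 without the span trend. ICAM1, an adhesion molecule for leukocytes, rose by 1.59 (SE 0.20) and BIRC3, an inhibitor of apoptosis, by 0.75 (SE 0.14).

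Of 27 damage-associated and unfolded protein response genes, 7 rose, 9 fell and 11 did not pass (7 and 9 adjusted over the list alone), with camera adjusted p = 0.647; the median was -0.002, 0.03 with libraries scaled by size alone, 0.08 with mitochondrial genes left out of the scaling and -0.09 without the span trend. ATF3, a stress-induced transcription factor, rose from 203 ± 40.3 to 1078 ± 41.5 normalized counts (log2 fold change 2.42, SE 0.13). HMGB1, a chromatin protein that acts as an alarm signal when released, fell from 10469 ± 1112 to 3799 ± 281 (log2 fold change -1.46, SE 0.09).

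**Figure D3:**
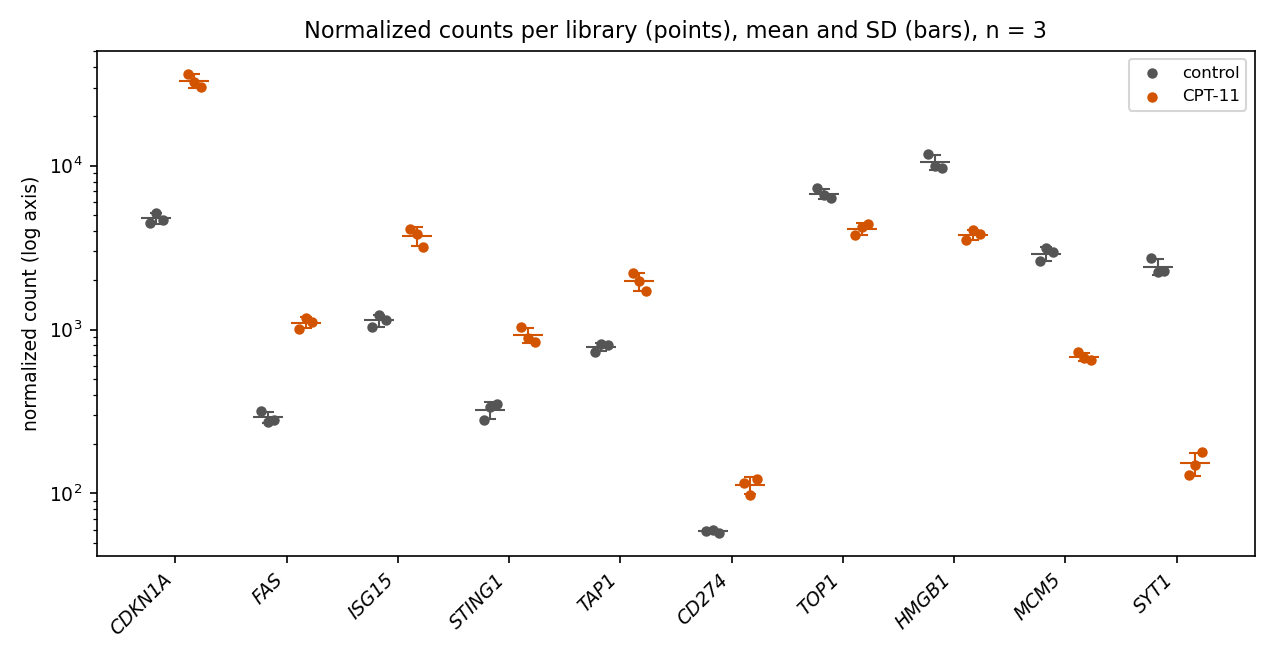
Normalized counts (vertical log axis) of 10 named genes (horizontal axis) in 3 control (grey) and 3 CPT-11 (orange) libraries; points are libraries, horizontal bars means and error bars SDs. The groups lie apart for each gene, with CDKN1A at 4774 ± 355 in controls and 33060.2 ± 3084 after CPT-11.

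Of 17 measured genes for the target and handling of irinotecan, 4 rose, 8 fell and 5 did not pass (4 and 8 adjusted over the list alone; median -0.12, and -0.04 with mitochondrial genes left out of the scaling; camera adjusted p = 0.299). TOP1, topoisomerase I itself (chromosome 20, 41028818 to 41124487), fell from 6745 ± 509 to 4124 ± 326 normalized counts (log2 fold change -0.71, SE 0.09, adjusted p = 4.23e-06), and TOP2A, the mitotic topoisomerase, by 1.43 on the log2 scale. CES2, a carboxylesterase that converts irinotecan to its active metabolite and is also on the p53 list, rose from 640.5 ± 10.4 to 1494 ± 124 normalized counts. Of 45 genes of double-strand break repair, 28 fell, 3 rose and 14 did not pass (28 and 3 adjusted over the list alone), with a median of -0.77. The list had camera adjusted p = 4.82e-09, and adjusted p = 0.139 with an estimated correlation.

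Of 51 replication-dependent histone genes 32 had a row and 12 entered the test. All 12 rose (12 adjusted over the list alone), with a median log2 fold change of 1.88. The filter on the mean over all 6 samples can admit a gene that only 1 group lifts over it. The list had camera adjusted p = 5.69e-07, and adjusted p = 0.0619 with an estimated correlation. The 32 histone genes with a row took 0.003% of reads in controls and 0.013% after CPT-11, and are close in sequence. The method of mRNA selection is not given, so how fully their transcripts were captured is not known. Their rise therefore need not reflect total histone transcripts. H2BC5, listed as HIST1H2BD, rose from 52.3 ± 5.3 to 259 ± 14.8 normalized counts (log2 fold change 2.29, SE 0.17). Of 34 apoptosis regulators, 19 rose, 5 fell and 10 did not pass (20 and 5 adjusted over the list alone), with a median of 0.34 and FAS as the most changed member. They had camera adjusted p = 0.000473, and adjusted p = 0.0844 with an estimated correlation; 10 members stand on other lists too. Of 10 pyroptosis and inflammasome genes, 5 rose, 1 fell and 4 did not pass (5 and 1 adjusted over the list alone; median 0.28, camera adjusted p = 0.143). NLRP1, an inflammasome sensor, rose by 1.96 (SE 0.19).

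Of 10 measured colon epithelial differentiation genes, 8 rose, 0 fell and 2 did not pass (8 and 0 adjusted over the list alone), with a median log2 fold change of 0.90. The list had camera adjusted p = 0.000203, and adjusted p = 0.153 with an estimated correlation. MUC2, the goblet cell mucin, had 2 reads over the controls and 327 over the CPT-11 libraries, a ratio of 163 after scaling by library size with an exact 95% interval of 44.8 to 1350 for counting error only. MUC2 entered the test through the CPT-11 group alone. Of 17 WNT target and intestinal stem cell genes, 6 rose, 5 fell and 6 did not pass (6 and 6 adjusted over the list alone; median 0.02, 0.06 with libraries scaled by size alone and 0.11 with mitochondrial genes left out of the scaling; camera adjusted p = 0.411), and TNFRSF19, a stem cell receptor also called TROY, had a log2 fold change of -2.94 (SE 0.44). Of 19 genes of epithelial-mesenchymal transition, 12 rose, 5 fell and 2 did not pass (13 and 5 adjusted over the list alone), with a median of 0.72. The list had camera adjusted p = 0.00341, and adjusted p = 0.0979 with an estimated correlation. SNAI2, a transcription factor of the list, rose by 3.31 (SE 0.52) from 11 reads over the controls, and LAMA3, a basement membrane laminin of epithelia, by 2.86. With 3.5 ± 3.5 normalized counts in controls, SNAI2 entered the test through the CPT-11 group alone. The 5 members that fell were VIM, the filament protein vimentin (-1.91), FN1, fibronectin (-1.34), the transcription factor genes ZEB1 (-0.85) and TWIST1 (68.8 ± 17.9 to 29.95 ± 11.1 normalized counts), and PLAUR, the urokinase receptor (-0.40).

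Of 24 cholesterol biosynthesis genes, 17 fell, 1 rose and 6 did not pass (19 and 2 adjusted over the list alone), with a median log2 fold change of -0.36. The list had camera adjusted p = 3.36e-05, and adjusted p = 0.0619 with an estimated correlation. INSIG1, a sterol sensor regulated with the pathway, fell from 2527 ± 68.7 to 854 ± 43.1 normalized counts (log2 fold change -1.57, SE 0.09). Of 21 glycolysis genes, 15 fell, 1 rose and 5 did not pass (15 and 1 adjusted over the list alone), with a median of -0.39. They had camera adjusted p = 0.000473, and adjusted p = 0.349 with an estimated correlation. PDK1, the kinase that restrains pyruvate dehydrogenase, had a log2 fold change of -1.58 (SE 0.13). Of 38 ribosome biogenesis genes, 19 rose, 7 fell and 12 did not pass (20 and 8 adjusted over the list alone), with a median of 0.25, and 0.16 without the span trend. They had camera adjusted p = 0.022, adjusted p = 0.222 with an estimated correlation, and adjusted p = 0.0523 without control replicate 3. DDX10, an RNA helicase of the list, went against it (-1.06, SE 0.12).

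Of 15 mitochondrially encoded genes, 11 rose, 0 fell and 4 did not pass (11 and 0 adjusted over the list alone), with a median log2 fold change of 0.53. The list had camera adjusted p = 3e-05, and adjusted p = 0.262 with an estimated correlation. Of 78 cytosolic ribosomal protein genes, 29 fell, 2 rose and 47 did not pass (25 and 2 adjusted over the list alone), with a median of -0.18, and -0.33 without the span trend. They had camera adjusted p = 0.00328, and adjusted p = 0.423 with an estimated correlation; with mitochondrial genes left out of the scaling, 15 fell and 5 rose, with a median of -0.10. Few markers of other cell types were measurable. Of 12 leukocyte markers with a row only ITGAM, an integrin chain of myeloid cells, entered the test and rose by 2.77 (8.84 ± 5.60 to 59.2 ± 1.56 normalized counts), while the pan-leukocyte gene PTPRC had 3 and 7 reads. ITGAM entered through the CPT-11 group alone. The fibroblast markers COL1A1, a collagen chain (0.85), and ACTA2, smooth muscle actin (1.59), rose, and THY1 had 4 and 2 reads. Of 3 tested endothelial markers ESAM, a junction protein, rose by 0.42, and PECAM1 had 9 and 2 reads and was not tested.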

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

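The edgeR test with TMM factors had been planned as the main test for a table of counts. Its use on recovered reads as an alternative to limma, and TMM scaling in limma, were chosen after seeing the data. So were leaving out both libraries numbered 1, leaving out mitochondrial genes and removal of the span trend. The other alternatives were set before. Across all of them 6812 to 8516 genes were called, against 8022, and no called list or named gene reversed its direction. Leaving out 1 sample at a time gave 6881 to 7971 genes. edgeR called 8157 genes, 7902 of them shared in direction. Leaving out both libraries numbered 1, which stood apart within their groups, gave 8516 genes, 4189 higher and 4327 lower. The median fold change of all tested genes (0.01, log2) became 0.04 with library size alone and 0.09 with mitochondrial genes left out and equal totals; the share of calls that were higher went from 49.1% to 52.8% and 57.9%. The planned run with DESeq2 size factors in the same test equals the deposited scaling, so those factors were used in edgeR. With the replicate number as a block, 6812 genes were called and no call of a list or named gene changed. Deviations of equally numbered samples had correlations of -0.23, -0.01 and -0.10, so the numbers give no ground to pair samples, and no sample correlated best with its own number. With an estimated correlation 0 of 23 lists passed, against 16 (23 by fry, which does not compare a list with other genes; 9 lists by camera at an unadjusted p below 0.05). Those adjusted p were 0.0619 for p53 targets, 0.0726 for G2/M, 0.0726 for G1/S, 0.0979 for interferon-stimulated genes, 0.094 for T cell and NK cell ligands and 0.122 for cytokines. Without members shared between lists, T cell and NK cell ligands (0.083) and cytokines (0.0779) did not pass; the tests then held 28 and 16 genes. The NF-kB list ranged from 0.0268, without CPT-11 replicate 3, to 0.159 when 1 sample was left out, and ribosome biogenesis reached 0.0523 without control replicate 3; the cause was not tested. Among the tested genes that the text names by rule, MICB passed in 6 of 20 settings (adjusted p 0.0116 to 0.179 over all), and the others kept their side of the threshold. Depth limits CGAS and CCL5, which had too few reads to enter the test.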

Other observations

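Of the tests in this part, those on symbol families, on long genes from library to library and on a common factor for mitochondrial transcripts were chosen after the result was seen. Protein-coding genes were grouped by the letters their symbols start with, and 168 families with at least 10 tested members were compared with all other genes. With camera's preset correlation 8 passed, and 0 did with an estimated correlation (adjusted p of 0.46 to 0.9 for these 8). With the estimated correlation 9 of the 168 had an unadjusted p below 0.05, about the number that chance gives. Among the 8 that passed with the preset were genes whose symbols start with KRT, mostly keratins, with 12 of 15 higher and 1 lower (adjusted p = 2.54e-05, median log2 fold change 1.73). KRT34 (0 ± 0 and 22.7 ± 6.6 normalized counts in controls and after CPT-11) and KRT5 (0.7 ± 1.2 and 22.8 ± 4.8) entered the test through the CPT-11 group alone. So did KRT17 (3.8 ± 3.3 and 54.5 ± 15.4) and KRT81 (4.1 ± 1.3 and 40.9 ± 9.1). Such genes could only come out higher, which adds to the count and to the family test. KRT7, a keratin of simple epithelia, rose from 84.3 ± 13.5 to 786 ± 73.7 normalized counts (n = 3), KRT15, a basal keratin, from 282 ± 21.9 to 941 ± 67.7, and KRT8, already abundant, from 28235 ± 1456 to 53996 ± 2533. KRT10, a keratin of upper skin layers, was the member that fell (-0.44), and it did not pass with mitochondrial genes left out of the scaling. POLR-named genes, mostly of RNA polymerase subunits, rose in 16 of 29 cases and fell in 1 (adjusted p = 0.0172, median 0.28). They included POLR1A, the large subunit of RNA polymerase I (0.91, SE 0.08), and POLR2A, that of RNA polymerase II (0.59, SE 0.10). POLR2J2 (7.2 ± 3.5 and 19.9 ± 10.3 normalized counts in controls and after CPT-11) entered through the CPT-11 group alone.

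NUP-named genes, mostly of nuclear pore proteins, fell in 18 of 21 cases with 0 higher (adjusted p = 2.54e-05, median -0.52), among them NUP210 (-1.12, SE 0.09) and NUP153 (-0.79, SE 0.10). Of 11 SRSF-named genes, of SR splicing factors, 9 fell and 1 rose (adjusted p = 0.0432, median -0.48). SRSF2 fell from 4326 ± 310 to 2094 ± 194 normalized counts, whereas SRSF8 rose from 1009 ± 78.5 to 2779 ± 115. Of 11 ADAM-named genes 7 fell and 0 rose (adjusted p = 0.0199), including the sheddase ADAM10 (-0.88, SE 0.10). The other families were KIF-named genes, mostly kinesins (17 of 34 lower, 4 higher, adjusted p = 0.001), MCM-named genes (9 of 10 lower, adjusted p = 1.17e-06) and genes whose symbols start with HIST (15 of 15 higher, adjusted p = 1.19e-06). HIST2H2BF, with 3.7 ± 0.4 normalized counts in controls and 21 ± 3.4 after CPT-11, entered the test through the CPT-11 group alone. So did HIST1H2BJ (4 ± 0.9 and 19.6 ± 8.5), HIST1H2BC (7.9 ± 2.2 and 27.5 ± 10.2) and HIST1H2BE (7.1 ± 3.4 and 18.9 ± 1.3). The filter thus fixed the direction of these HIST members. Members of the KIF, MCM and HIST families also stand on the G2/M, G1/S or histone lists. Members of the fixed lists were not left out of any family, so the 8 families are not separate evidence. The median of each of these 8 families kept its sign under the scalings by library size, by TMM and without mitochondrial genes.

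The fall of long genes may be a hypothesis worth following, since trapped topoisomerase I blocks elongating RNA polymerase and a longer gene offers more places for a block. Spearman's rho of log2 fold change with genomic span was -0.32 across 13202 genes, which are not independent replicates; it was -0.257 in the CPT-11 library where it was weakest, against -0.248 to 0.25 between control libraries and -0.3 to 0.288 between CPT-11 libraries, so rho by itself does not set that library apart from differences within a group. Partial rank correlations argue against mature transcript length (-0.278 given it), transcript GC content (-0.264) and read depth per gene (-0.318) as the whole of the trend. A trend that merely differs from library to library is argued against by the size of the change in genes of at least 300 kb: the largest median between control libraries (0.067) was 0.063, and that between CPT-11 libraries (-0.128, sample 1) 0.121, of the smallest in a CPT-11 library against the controls (-1.06). Transcription itself was not measured, so the hypothesis stays open, and removing the trend left the p53 list at a median of 1.23 and the G2/M list at -1.55 but took interferon-stimulated genes from 0.35 to 0.22, ribosome biogenesis from 0.25 to 0.16, MHC class I from 0.12 to 0.05, NF-kB from 0.22 to 0.07 and ribosomal protein genes from -0.18 to -0.33.

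The larger share of mitochondrially encoded transcripts could be a by-product of fewer nuclear transcripts per cell, which would raise all 15 by 1 factor. Against that as the whole account, 8 of the 15 lay more than 2 SE from their common log2 fold change of 0.53, with MT-RNR1, the small ribosomal RNA, at 1.80 (SE 0.10) and MT-CO2, a cytochrome oxidase subunit, at 0.17 (SE 0.10). Carry-over of the 2 ribosomal RNAs is not enough either, since the 13 mRNAs alone went from 6.14% ± 0.27 to 8.34% ± 0.49 of reads (SD, n = 3), a ratio of 1.36. A lower total of nuclear RNA acting together with unequal changes stays open, because the values used here carry no absolute scale.

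Some genes that dividing cells use heavily were listed with few reads, and a candidate cause is that reads on exons shared with an overlapping gene were not counted. Over 4 lists, 5 members lay below 0.1 of their list's median: PRC1, a mitotic spindle protein, with 15.4 normalized counts, POLA2, a polymerase alpha subunit, with 80.4, the glycolytic enzyme ALDOA with 48.7, and the ribosome biogenesis factors NOP2 with 29.7 and PPAN with 130.8. Their median share of exonic bases held in common with another gene was 54.4%, against 0% for the 142 other members, a difference of 54.4 percentage points. A permutation test of the difference in mean share, not in median share, gave one-sided p = 1e-05, the smallest that 100000 resamples can give. The counting rule itself is not given in the sources used here, so it stays open; if it held, fold changes of such genes would rest on the unshared part of their exons.

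The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 8022 changed genes, 3939 higher, 4083 lower and 2271 changed at least 2-fold. For each of these counts 1 of the 10 splits, the real one, reached that number, and the highest of the other splits gave 0. Each other split mixes the 2 groups, so any difference between them, whatever its cause, widens the spread within its sets of 3. The 0 there therefore says nothing of the cause.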
